A study of Homo sapiens with 9 samples.

How the data were processed

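Gene expression was measured with Affymetrix whole-transcript arrays in HL-60 clone 15, an established human promyelocytic leukaemia cell line whose clone 15 is used as a model of eosinophil precursors. The cells carried a lentiviral construct for RHOH, a gene of haematopoietic cells, or for GFP, a fluorescent protein used as a control, each switched on by 100 nM 4-hydroxytamoxifen (4-OHT). 4-OHT is the active metabolite of tamoxifen and a ligand of the oestrogen receptor. The labels place the 9 arrays in 3 groups of 3: RhoH cells without 4-OHT (uninduced), RhoH cells with 4-OHT (induced) and GFP cells with 4-OHT. The design text calls the 3 samples of a group biological replicates. The group and replicate of each array were taken from the sample titles. No 2 arrays held identical values. There was no GFP group without 4-OHT among the arrays used here, so an effect of 4-OHT, a difference between the transduced cell populations and leak of the construct are not separated by this design.

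The authors deposited 1 table of log2 expression values for 43550 probe sets. Per the submitters' processing notes, Affymetrix Power Tools, RMA and limma were used, with versions not given in the sources used here. RMA corrects the background, quantile-normalizes the probes across arrays and summarises them per probe set on the log2 scale. A fold change between groups is therefore a difference of log2 values, and low signals are compressed towards the background. The deposited log2 values ran from about 2 to 14 with similar medians on all arrays, and no further normalization was applied. The number of arrays limits the precision, and the values hold no counts from which a depth could be read.

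Probe sets were named through a table of the platform annotation, which gave 1 gene symbol for 15659 probe sets, several for 0 and none for 27891. All 15659 Entrez identifiers were found in a RefSeq gene table of assembly GRCh38.p14, through which symbols and gene classes were taken. The deposited values name no genome build, so no coordinates are given. Where a gene had over 1 probe set (521 genes), the one with the highest mean over the 9 arrays was used, which left 14778 genes, of which 11902 were protein-coding, 1368 lncRNA and 1022 miRNA genes. A probe set without a symbol in that table is unnamed here, not without a gene.

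Group differences were tested with limma 3.58.1 in R 4.3.3: a linear model with the 3 group means over all 9 arrays, default empirical Bayes moderation (6 residual degrees of freedom and a prior of 3.86), and Benjamini-Hochberg adjustment over the 14778 genes within a comparison. A gene was called at an adjusted p under 0.05. The comparisons were induced minus uninduced RhoH, induced RhoH minus GFP, and uninduced RhoH minus GFP. Genes called in both comparisons of induced RhoH with the same sign were counted as well. Single-gene values for RHOH also have a two-sided exact permutation test, whose smallest p with 3 arrays against 3 is 0.1. All adjusted p-values for genes are from limma. Over all 14778 genes, the arrays of the 2 groups did not overlap for 2149, 3325 and 5511 genes in the 3 comparisons in that order, where chance gives 10% of genes. Errors of group means are SD over 3 arrays, and errors of fold changes are the standard error (SE) of the fit.

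The design, the alternatives, 22 gene lists and the rule for naming genes were fixed before the data were examined. The lists hold 437 symbols, of which 280 were measured as named genes, and the others are not analysed here. Of the lists, 1 is not reported here. The other 21 are eosinophil genes, azurophil granule genes, specific granule and neutrophil maturation genes, monocyte and macrophage markers, haematopoietic transcription factors, actin regulators, adhesion and migration receptors, NF-kB target genes, cytokine receptor and STAT5 genes, interferon-stimulated genes, cell cycle genes, apoptosis genes, cholesterol synthesis genes, oestrogen receptor target genes, unfolded protein and amino acid response genes, hypoxia and glycolysis genes, immediate early genes, lymphoid markers, erythroid and megakaryocyte markers, mast cell and basophil markers, and ribosomal protein genes. For each list the called members were counted over all genes tested and adjusted over the list alone. Each list was tested against the other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists within a comparison, and again with an estimated correlation. The test fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, was an alternative. Some symbols belong to 2 lists. The genes named are RHOH and, for each comparison of induced RhoH, the 10 highest and 10 lowest fold changes among called genes whose 2 groups of arrays did not overlap. For uninduced RhoH against GFP 5 and 5 are named, and among the genes called in both comparisons the 10 highest and lowest by the smaller of the 2 fold changes. Up to 4 members of each list and comparison are named as well, called members first. Noncoding, antisense and uncharacterised symbols were counted but skipped in naming.

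The comparisons share groups of arrays. Chance overlap and covariance were therefore simulated 100 times with noise of the fitted size, no effects and the same shared arrays. The fitting code was tested on simulated data with the real genes, 50 changed per size. For induction, 40% of genes changed by 0.5 on the log2 scale and 94% of those changed by 1 were recovered with the right sign, and 36% and 96% for RhoH against GFP. In both, 100% were recovered at 2 and at 3. Of the unchanged genes, 6, 5 and 0 were called in induction, RhoH against GFP and uninduced RhoH against GFP. Noise in that simulation was independent between genes.

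The alternatives were moderation with a trend and robust prior, leaving out the dimmest 40% of genes, testing all probe sets, fitting only the 6 arrays compared, the replicate number as a block, quantile normalization of the tested genes again, centring each array on the median of the tested genes, array weights, a fold change of at least 2 as a further condition (1 on the log2 scale), and leaving out each array. The fold change condition was applied to the counts of called genes only, not to single genes or lists. A named gene among the dimmest 40% has no value with these left out, and kept calls refer to the alternatives that hold the gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.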

Results

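Total RNA of 9 samples of HL-60 clone 15 cells was profiled on arrays, 3 samples of RhoH cells without 4-OHT, 3 of RhoH cells with 100 nM 4-OHT and 3 of GFP cells with 100 nM 4-OHT. The study set out to find which genes RhoH changes, with uninduced RhoH cells and induced GFP cells as 2 controls. Median log2 signal over all probe sets was between 5.43 and 5.55 on the 9 arrays. Pearson correlations were taken across all probe sets, which are not independent replicates. Within a group they were 0.995 to 0.996 for GFP, 0.980 to 0.995 for uninduced RhoH and 0.974 to 0.983 for induced RhoH. The replicate 1 arrays of both RhoH groups deviated from the others of their groups and correlated at 0.987 with each other. Induced RhoH replicate 3 deviated from its group mean as much as induced RhoH replicate 1 (SD over genes 0.204 and 0.200). Their array weights were 0.275 and 0.334. The GFP arrays deviated least from their group mean, with an SD over genes of 0.090 to 0.096 against 0.130 to 0.206 on the RhoH arrays. Counts of called genes are also given without the 2 replicate 1 arrays, a setting chosen after seeing the data, and for the lists where they changed by over 1.5 times.

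RHOH itself (probe set 16966214), the gene carried by the construct, was not highest where the labels place its induction. Its log2 signal was 5.21 ± 0.06 (SD, n = 3) in the arrays labelled uninduced RhoH, 5.59 ± 0.14 in those labelled induced RhoH and 5.93 ± 0.02 in those labelled GFP. It was 1.30-fold higher with 4-OHT in RhoH cells (log2 fold change 0.38, SE 0.09, limma adjusted p = 0.0451). In the arrays labelled induced RhoH it was lower than in those labelled GFP by a log2 fold change of -0.33 (SE 0.09, adjusted p = 0.0717), and in those labelled uninduced RhoH by -0.72 (SE 0.09, adjusted p = 0.000420). In each of the 3 comparisons the arrays did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. RHOH lay between percentile 25.1 and 41.5 of the tested genes on these arrays. The call for induction was lost when 8 of the 9 arrays were left out in turn, with adjusted p between 0.0781 and 0.171, and held without induced RhoH replicate 3 (0.0184). Without induced RhoH replicate 2 the difference from GFP passed the threshold (-0.40, adjusted p = 0.0495). Over all alternatives the adjusted p ran from 0.00542 to 0.192 for the induction and from 0.0467 to 0.236 against GFP. The positions of its probes were not used here, so how much of the construct's transcript the probe set reads is not known. Since mean RHOH was higher in the arrays labelled GFP than in those labelled induced RhoH, though not past the threshold, every direction below is that of the arrays as labelled.

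**Figure D1:**
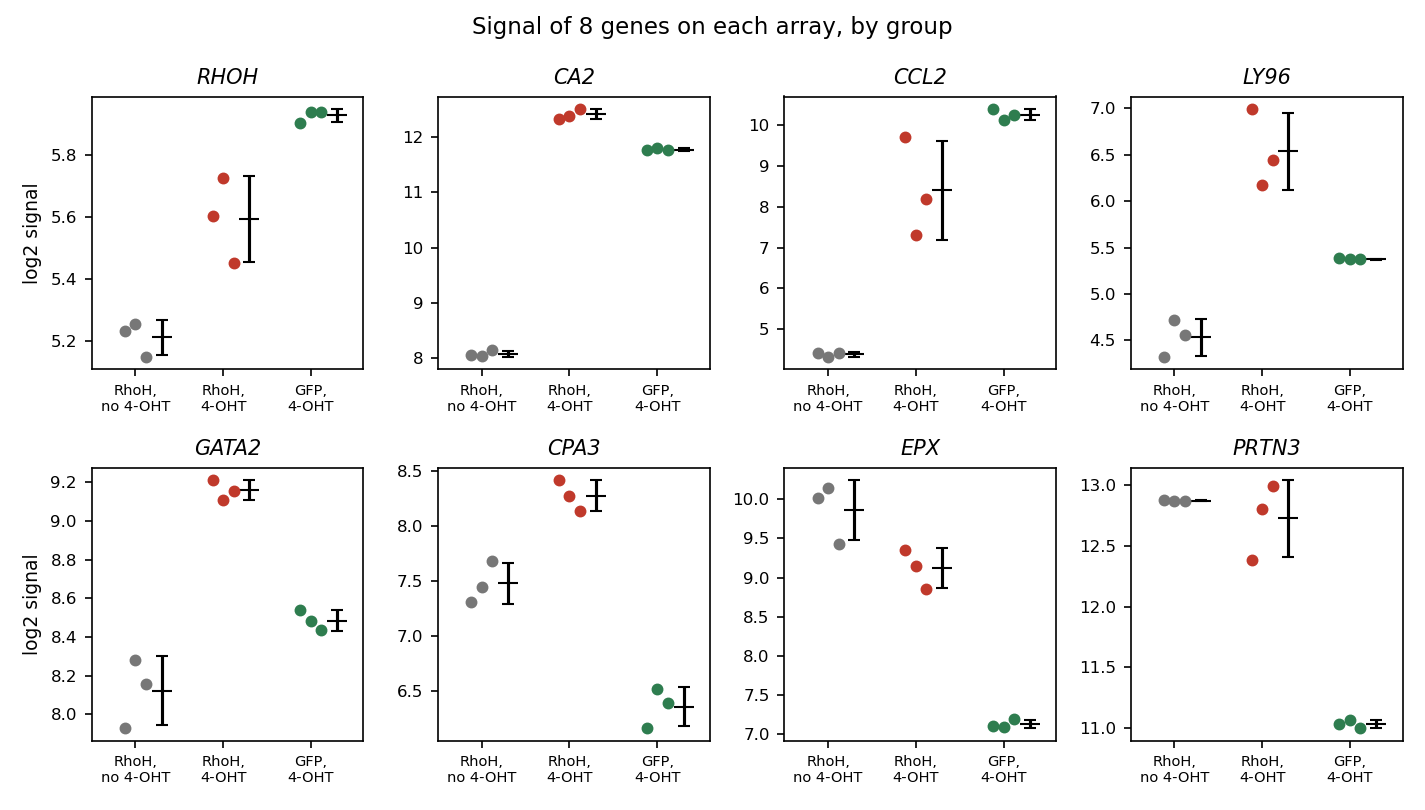
Log2 signal of 8 genes on each of the 9 arrays (points), with the group mean and SD beside them (bar and whiskers, n = 3), for RhoH cells without 4-OHT, RhoH cells with 4-OHT and GFP cells with 4-OHT, each panel with its own vertical range. RHOH was highest in the arrays labelled GFP (mean 5.93), CA2, LY96, GATA2 and CPA3 were highest in those labelled induced RhoH, and EPX and PRTN3 were higher in both RhoH groups than in GFP.

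More genes were higher than lower with 4-OHT in RhoH cells. Of 14778 genes, 558 differed between the arrays labelled induced and uninduced RhoH, 447 higher and 111 lower, of which 99 and 3 by at least 2-fold. CA2, which encodes carbonic anhydrase II, had the highest fold change among the called genes, from 8.08 ± 0.06 to 12.41 ± 0.09 on the log2 scale (SD, n = 3), or 20.2-fold (adjusted p = 2.53e-09). The monocyte chemoattractant CCL2 rose 16.2-fold from 4.39 ± 0.06 to 8.40 ± 1.21, with a wide spread between the induced arrays (adjusted p = 0.000984). Its log2 fold change of 4.02 was 3.37 without induced RhoH replicate 1. Its uninduced signal was below that of RHOH on each of these arrays, and compression towards the background can understate such a fold change. The AP-1 subunit JUN rose 12.1-fold (adjusted p = 3.99e-05).

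The other 7 of the 10 highest genes rose by 2.07 to 3.15 on the log2 scale. They were the chemokine CCL1 (2.85), the sialic acid-binding receptor SIGLEC6 (2.62), the signalling adaptor LAT (2.43), the surface glycoprotein CD48 (2.23), the metalloprotease ADAM28 (2.09), the co-stimulatory ligand CD86 and ANXA2P2, a pseudogene of ANXA2. All 10 kept their calls in each alternative run for single genes. The 10 lowest fell by less, from -0.85 for the kinase gene MATK to -1.05 for ANKRD18A. They included POLR3G, a subunit of RNA polymerase III (-1.03), IFT57, a protein of intraflagellar transport (-0.95), and GCSH of the glycine cleavage system (-0.96). The remaining 5 were LRRC34, PODXL2, ASIC1, CCDC169-SOHLH2 and ROPN1L. Of these 10, only POLR3G and IFT57 kept their calls in every alternative run for single genes. The other 8 lost theirs where only the 6 arrays compared were fitted (adjusted p = 0.0589 to 0.144). Of the 8, 7 (not CCDC169-SOHLH2) also lost theirs without uninduced RhoH replicate 3 (adjusted p = 0.0652 to 0.151), 6 of these (not PODXL2) without uninduced RhoH replicate 2 (0.0547 to 0.138), and PODXL2 without both replicate 1 arrays (0.0628). ANKRD18A, GCSH, ASIC1, ROPN1L and MATK lost theirs with all probe sets tested (0.0561 to 0.103) and when some of the other arrays were left out (up to 0.0903).

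Among the fixed lists, 6 were higher with 4-OHT and 2 lower in RhoH cells by camera at the preset correlation, and none of the 8 calls held with an estimated correlation (adjusted p = 0.470 for each). With fry only the interferon list of these 8 passed (adjusted p = 0.0251). No list called by camera in any comparison changed the sign of its median under the 2 scaling alternatives. Of 10 immediate early genes, which respond within minutes to growth and stress signals, JUN and JUNB (1.16) rose and 8 did not pass, among them FOS at 1.40 (adjusted p = 0.0994) and EGR1 at 1.24 (adjusted p = 0.170). The list had 5 higher and 0 lower when adjusted over the list alone, and camera gave an adjusted p of 0.000134. Of 16 interferon-stimulated genes, IFIT3 (1.11) and the RNA sensors RIGI (0.67) and IFIH1 (0.53) rose, with 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00446, 0.126 with the dimmest genes left out). Of 16 NF-kB target genes, CCL2 and IRF1 (1.57) rose and CXCL8 was at 1.29 (adjusted p = 0.0628), with 3 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.00915, 0.0856 without induced RhoH replicate 3). Of 18 apoptosis genes, APAF1 (0.90), the core of the apoptosome, and BCL2L11 (0.65), which encodes the death-promoting BIM, rose, with 2 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.00446). Of 14 actin regulators, the guanine nucleotide exchange factor DOCK8 (0.58) and WAS (0.50) rose, with 3 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.00642). Of 17 specific granule and neutrophil maturation genes, HP, which encodes haptoglobin, rose (1.46), with 3 higher and 0 lower when adjusted over the list alone, and the camera call (adjusted p = 0.0499) was lost in most alternatives.

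The list of 13 cholesterol synthesis genes was lower by camera (adjusted p = 0.00583, 0.178 without induced RhoH replicate 1), although its 1 called member, INSIG1, which restrains cholesterol synthesis, rose (0.73). HMGCS1 was at -0.45 (adjusted p = 0.0523) and SQLE at -0.45 (adjusted p = 0.0866), and the list had 1 higher and 3 lower when adjusted over the list alone. Ribosomal protein genes were lower by camera (adjusted p = 0.0499) with none of 13 members called by limma (0 higher and 0 lower at an unadjusted p under 0.05, 0 higher and 0 lower when adjusted over the list alone), and that call too was lost in most alternatives.

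Another 13 lists did not pass camera in this comparison, though single members changed. Of 12 monocyte and macrophage markers, CD86 and the lysosomal glycoprotein CD68 (1.11) rose (2 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0610). Of 12 adhesion and migration receptors, the chemokine receptor CCR1 (1.62) and the formyl peptide receptor FPR2 (0.85) rose (3 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0571). Of 6 mast cell and basophil markers, the granule protease gene CPA3 (0.79) and the stem cell factor receptor KIT (0.67) rose (2 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.107). Of 16 haematopoietic transcription factors, GATA2 rose (1.04) and MYC fell (-0.85) (3 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.394). Of 14 cytokine receptor and STAT5 genes, CCND3 (0.77) and PIM1 (0.64) rose and CCND2 fell (-0.69 at the probe set used and -0.19 at another; 2 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0771). Of 12 unfolded protein and amino acid response genes, CRELD2 rose (1.04) and ASNS (-0.59), MANF (-0.58) and SDF2L1 (-0.55) fell (1 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.141).

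Of 9 azurophil granule genes, CTSG, which encodes cathepsin G, fell (-0.83), with 0 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.0571). Of 7 eosinophil genes none was called by limma (1 higher and 1 lower at an unadjusted p under 0.05, 1 higher and 1 lower when adjusted over the list alone), and EPX, the eosinophil peroxidase gene, was at -0.75 (adjusted p = 0.0560). Camera gave the list an adjusted p of 0.987 (upwards although the median was -0.02 and the mean -0.03). Of 25 cell cycle genes, CCNE2 rose (0.79; 1 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0729). Of 12 oestrogen receptor target genes, RET fell (-0.82; 1 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.330). Of 9 lymphoid markers, LAT rose (1 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.837, upwards with a median of -0.05 and a mean of 0.23). No member was called by limma among 12 hypoxia and glycolysis genes (1 higher and 2 lower at an unadjusted p under 0.05, 1 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.366) and 5 erythroid and megakaryocyte markers (0 higher and 0 lower at an unadjusted p under 0.05, 0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.837, downwards with a median of -0.01 and a mean of 0.01). The median of the transcription factor list, 0.01, changed sign under scaling.

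Several of these list results in the induction depended on single arrays. BCL2L11, ASNS and MANF lost their calls when any 1 array other than induced RhoH replicate 3 was left out (adjusted p up to 0.0985, 0.107 and 0.0776), and PIM1 with any other than induced RhoH replicate 1 (0.0888). IFIH1 kept its call only without uninduced RhoH replicate 2 or induced RhoH replicate 1 (up to 0.118 otherwise). INSIG1 lost its call without uninduced RhoH replicate 1 or 3 or induced RhoH replicate 2 or 3 (0.0650), RET without uninduced RhoH replicate 2 or 3 or induced RhoH replicate 1 or 2 (0.0888). WAS and JUNB lost theirs without uninduced RhoH replicate 1 or 3 (0.0884 and 0.0808) and CCND2 without uninduced RhoH replicate 3 (0.0650). Without both replicate 1 arrays, the calls of CTSG (0.0541), WAS (0.0618), PIM1 (0.0657), BCL2L11 (0.114), ASNS (0.168), MANF (0.112) and CPA3 (0.0533) were lost. Azurophil granule genes then had no called member instead of 1, unfolded protein and amino acid response genes 1 lower instead of 3, and the higher members fell from 2 to 1 for actin regulators, cytokine receptor and STAT5 genes, apoptosis genes and mast cell and basophil markers. Cholesterol synthesis genes then had 1 lower and hypoxia genes 1 higher instead of 0. Camera, in turn, passed for some of the 13 lists under alternatives. Upwards these were monocyte and macrophage markers with the dimmest genes left out (0.0187) and without induced RhoH replicate 2 (0.0280), and adhesion and migration receptors with the dimmest genes left out (0.0249) and without uninduced or induced RhoH replicate 2 (0.0379 and 0.0222). Cytokine receptor and STAT5 genes passed without uninduced RhoH replicate 2 (0.0379) and cell cycle genes without induced RhoH replicate 1 (0.00859) or both replicate 1 arrays (0.0439). Downwards, azurophil granule genes (0.0263) and unfolded protein and amino acid response genes (0.0415) passed without induced RhoH replicate 3. Fry passed for monocyte and macrophage markers and for mast cell and basophil markers (0.0251 for each).

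The count of 558 was 953 (588 higher and 365 lower) after quantile normalization of the tested genes again, so that 61.7% instead of 80.1% of the calls were higher, 950 with array weights and 190 (182 higher, 8 lower) when only the 6 arrays compared were fitted. It was 304 (287 higher, 17 lower) without uninduced RhoH replicate 3 and 371 (327 and 44), 368 (321 and 47) and 355 (310 and 45) without GFP replicate 1, 2 or 3, which enter the estimate of the spread. The 111 lower genes became 31 without uninduced RhoH replicate 2 (399 higher) and 61 without induced RhoH replicate 1 (413 higher), but 280 without induced RhoH replicate 3 (386 higher). The size of the lean to higher genes thus depended on single arrays. Without both RhoH replicate 1 arrays it was 557 (413 higher, 144 lower), of which 434 were called the same way with all arrays. At an unadjusted p under 0.05, 2139 genes differed.

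The comparison of induced RhoH with GFP cells, both with 4-OHT, asks which genes differ when the drug is the same, although the 2 transduced populations differ as well. Azurophil granule genes were higher in the arrays labelled induced RhoH. Of 14778 genes, 664 differed, 257 higher and 407 lower in RhoH cells, of which 32 and 84 by at least 2-fold. CEACAM8, an adhesion molecule of granulocytes, was 10.30 ± 0.23 in RhoH and 7.81 ± 0.03 in GFP cells on the log2 scale (SD, n = 3), 5.63-fold higher (adjusted p = 6.1e-06). ZNF141, a zinc finger gene, was 9.40-fold lower in RhoH cells, at 4.83 ± 0.04 against 8.06 ± 0.08 (adjusted p = 1.85e-06). Its signal in RhoH cells was low, below the mean of RHOH there, and compression towards the background can understate such a fold change.

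The other 9 highest genes were EPX (1.99), CPA3 (1.91), the desmosomal cadherin DSG2 (1.72), the neutrophil proteases PRTN3 (1.69) and CTSG (1.64), ASS1 of arginine synthesis (1.62), the neuropeptide galanin gene GAL (1.62), CLC, the Charcot-Leyden crystal protein of eosinophils and basophils (1.55), and BICC1 (1.51). CLC lost its call when any 1 GFP array was left out (adjusted p = 0.0938, 0.0956 and 0.117), and the other 9 of the 10 kept theirs in each alternative run for single genes. The other 9 lowest were CEMIP2, a cell surface hyaluronidase (-2.87), DPYD of pyrimidine breakdown (-2.75), the p53-inducible TP53INP1 (-2.71), LACC1 (-2.54), the cell surface protein CDON (-2.38), the interferon-inducible GTPase GBP4 (-2.35), MTCL1 (-2.21), OGFRL1 (-1.78) and FPR2 (-1.77). All 10 of the lowest also kept theirs.

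Azurophil granule genes, which mark the promyelocyte stage, moved together: 7 of 9 were higher in RhoH cells and none lower, with the same numbers adjusted over the list alone. Beside PRTN3 and CTSG they included AZU1 (1.33) and CST7 (1.22). Camera gave an adjusted p of 6.43e-12, and 0.0404 with an estimated correlation, the only list of this comparison whose call held with it. Of 7 eosinophil genes, EPX, CLC and the histamine receptor HRH4 (1.00) were higher, with 4 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.000332, adjusted p = 0.0504 with an estimated correlation). Of 16 haematopoietic transcription factors, GATA2 (0.67), MYC (0.76), MYB (0.57), XBP1 (0.50) and GFI1 were higher, with 6 higher and 0 lower when adjusted over the list alone (camera adjusted p = 7.3e-05, adjusted p = 0.0504 with an estimated correlation).

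Of 12 adhesion and migration receptors, 4 were lower in RhoH cells, the chemoattractant receptors FPR2 and C5AR1 (-1.46) and the adhesion molecules ICAM1 (-0.69) and CD44 (-0.65), with 1 higher and 6 lower when adjusted over the list alone (camera adjusted p = 6.54e-05, adjusted p = 0.119 with an estimated correlation). Of 16 NF-kB target genes, the chemokine CCL4 (-0.97), the cyclooxygenase gene PTGS2 (-0.94) and ICAM1 were lower and CCL2 was at -1.85 (adjusted p = 0.0504), with 0 higher and 4 lower when adjusted over the list alone (camera adjusted p = 6.54e-05, adjusted p = 0.277 with an estimated correlation). Ribosomal protein genes were higher by camera (adjusted p = 0.000112, adjusted p = 0.277 with an estimated correlation) with no member called by limma over all genes (8 higher and 0 lower at an unadjusted p under 0.05) and 5 higher and 0 lower when adjusted over the list alone. Of 12 unfolded protein and amino acid response genes, 4 were higher, including the asparagine synthetase gene ASNS (0.92), MANF (0.64) and XBP1, and CRELD2 was lower (-1.30), with 6 higher and 1 lower when adjusted over the list alone. The camera call of that list (adjusted p = 0.0475, adjusted p = 0.765 with an estimated correlation) was lost in most alternatives.

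Another 14 lists did not pass camera between induced RhoH and GFP cells. Those of specific granule genes (median -0.01, mean 0.15, camera upwards) and of hypoxia genes (median 0.05, mean -0.0020, camera upwards) differed in sign between measures, and the cholesterol list's median of 0.01 changed sign under scaling. Single members were lower in RhoH cells, among them CD14 of the monocyte and macrophage markers (-1.35), BIRC2 of the apoptosis genes (-0.87), XAF1 (-0.74) and IFIT3 (-0.67) of the interferon-stimulated genes, SIAH2 of the oestrogen receptor targets (-1.56), the hexokinase gene HK1 (-0.93), KIT (-0.53) and HP (-1.13). Others were higher, among them the apoptosis inhibitor BCL2 (0.99), CCND2 (1.43, and 0.60 at its other probe set), RET (0.98), CEACAM6 (1.10), NDRG1 (0.69) and SQLE of cholesterol synthesis (0.70). No member was called by limma among immediate early genes (0 higher and 2 lower at an unadjusted p under 0.05), lymphoid markers (0 higher and 0 lower at an unadjusted p under 0.05), erythroid and megakaryocyte markers (0 higher and 0 lower at an unadjusted p under 0.05) and cell cycle genes (3 higher and 0 lower at an unadjusted p under 0.05).

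Here too some list results depended on single arrays. Against GFP, PTGS2 lost its call when any 1 array other than GFP replicate 1 was left out (adjusted p up to 0.104). CCL4 lost its call without uninduced RhoH replicate 2 or 3, induced RhoH replicate 1 or 2 or GFP replicate 1 or 3 (0.0975), and IFIT3 when any 1 induced RhoH or GFP array was left out (0.102). MYB lost its call without induced RhoH replicate 1 or 2 or GFP replicate 1, 2 or 3 (0.105), XBP1 without GFP replicate 1, 2 or 3 (0.0739). MANF lost its call without GFP replicate 1 or 3 (0.0784), SQLE without GFP replicate 2 or 3 (0.0634) and KIT without GFP replicate 1 (0.0506). Without both RhoH replicate 1 arrays, MYB (0.0510), CCL4 (0.102) and PTGS2 (0.102) lost theirs, while CCL2 passed the threshold at -2.51 (adjusted p = 0.00165). It did so at the same fold change without induced RhoH replicate 1 alone (0.000530). It also passed with the trend and robust prior, the dimmest genes left out, the replicate block, arrays centred on their median, array weights and protein-coding genes only. Without both replicate 1 arrays, the called members rose from 1 to 2 for lower monocyte and macrophage markers, higher cytokine receptor and STAT5 genes and higher apoptosis genes. They rose from 0 to 2 for higher ribosomal protein genes and 0 to 1 for higher adhesion receptors and higher cell cycle genes, and fell from 2 to 1 for higher oestrogen receptor targets. Among the 14 lists, monocyte and macrophage markers passed camera downwards with the dimmest genes left out (0.0234) and without induced RhoH replicate 1 (0.0299) or GFP replicate 2 (0.0283). Immediate early genes did without induced RhoH replicate 3 (0.00374) and interferon-stimulated genes without GFP replicate 3 (0.0488), while mast cell and basophil markers passed upwards with the dimmest genes left out (0.0120). Fry passed for monocyte and macrophage markers (0.0466), interferon-stimulated genes (0.0238) and mast cell and basophil markers (0.0194). Of the lists called by camera it did not pass for NF-kB target genes (0.0545) and unfolded protein and amino acid response genes (0.216).

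The count of 664 was 1176 (509 higher, 667 lower) with array weights, and 302 (102 higher, 200 lower), 279 (103 and 176) and 285 (91 and 194) without GFP replicate 1, 2 or 3. Without both RhoH replicate 1 arrays it was 990, of which 606 were called the same way with all arrays, and the balance of 512 higher and 478 lower no longer leaned to lower genes. Nor did it without induced RhoH replicate 1 alone, with 615 genes, 319 higher and 296 lower. At an unadjusted p under 0.05, 2419 genes differed.

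**Figure D2:**
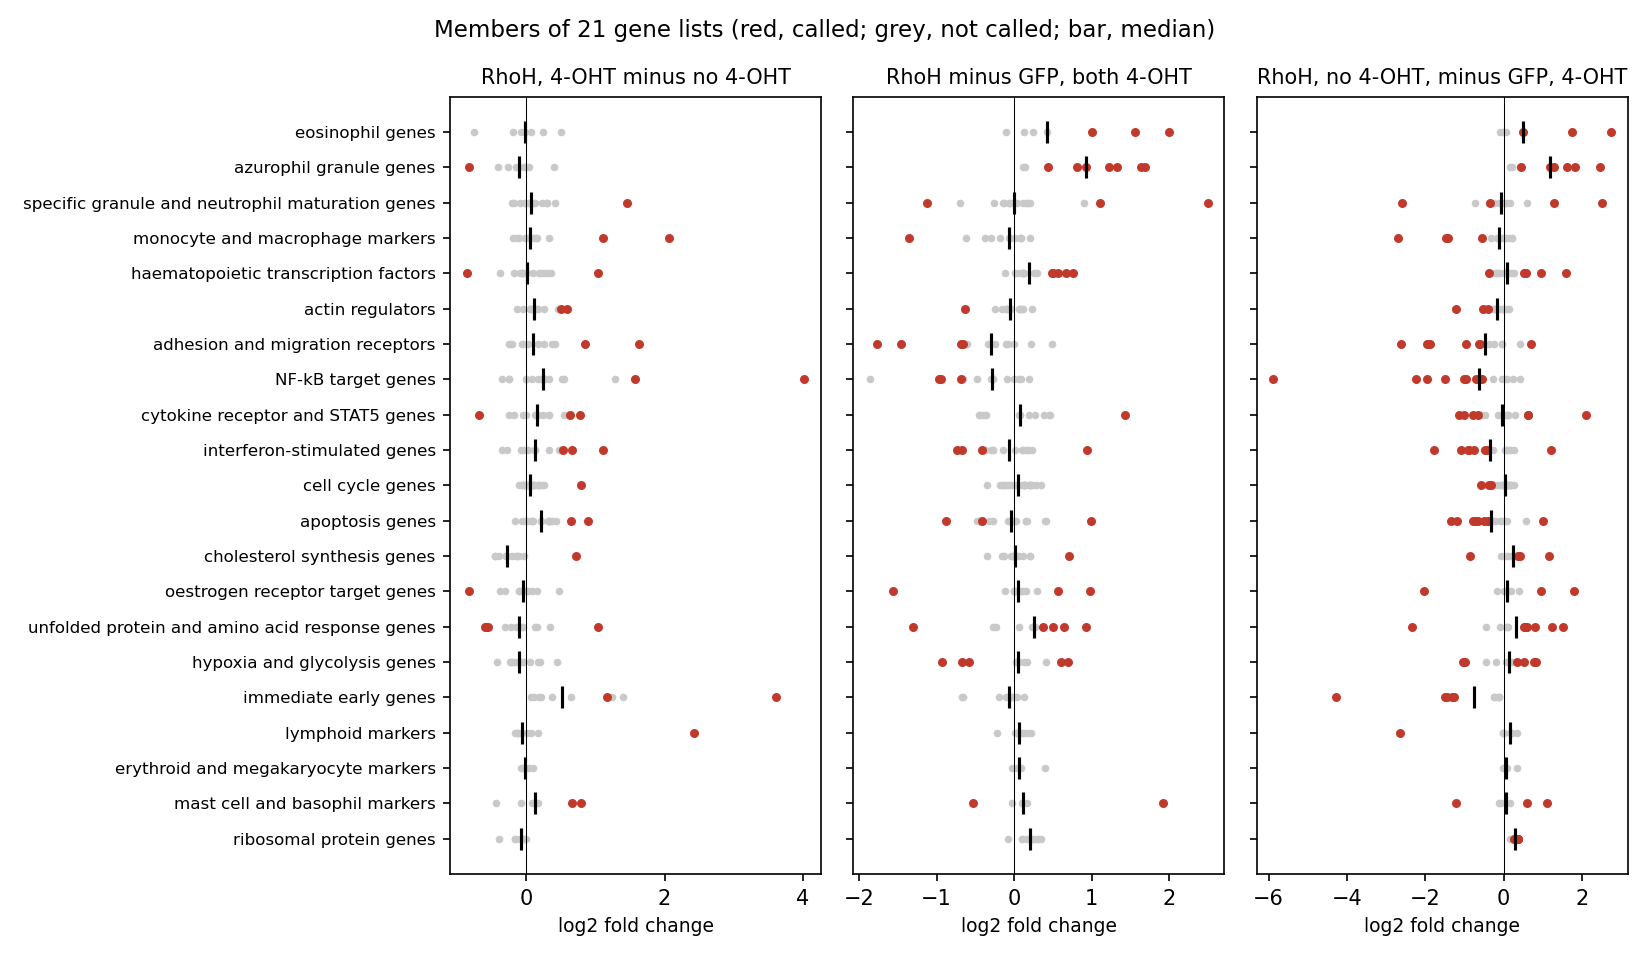
Log2 fold changes of the measured members of 21 gene lists (points; red, called at a limma adjusted p under 0.05; grey, not called) with the median of each list (black bar), for induced minus uninduced RhoH, induced RhoH minus GFP, and uninduced RhoH minus GFP. Azurophil granule genes had a median of 0.93 against GFP in induced and 1.19 in uninduced RhoH cells, while NF-kB target genes had medians of -0.29 and -0.63.

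As labelled, the 2 control groups differed from each other in more genes than either did from induced RhoH. With the labels of the 2 groups with 4-OHT exchanged, the controls would differ in 558 genes, and induced from uninduced RhoH in 2258. Between the arrays labelled uninduced RhoH and those labelled GFP with 4-OHT, 2258 genes differed, 888 higher and 1370 lower in uninduced RhoH, of which 111 and 353 by at least 2-fold. CCL2 was 4.39 ± 0.06 in uninduced RhoH against 10.26 ± 0.13 in GFP cells on the log2 scale (SD, n = 3), 58.6-fold lower (adjusted p = 1.74e-05). Its uninduced signal was low, below that of RHOH on each of these arrays, and compression towards the background can understate such a fold change. CEMIP2 (-4.55), JUN (-4.27), CDON (-4.16) and CA2 (-3.70) followed among the lowest, and EPX (2.73), CEACAM8 (2.50), CTSG (2.47), ASS1 (2.44) and GAL (2.31) were the highest, all 10 called in each alternative run for single genes.

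By camera, 5 lists were higher in uninduced RhoH than in GFP cells and 7 lower, and none of the 12 passed with an estimated correlation (lowest adjusted p = 0.105, for azurophil granule genes). Of 9 azurophil granule genes 6 were higher (8 higher and 0 lower when adjusted over the list alone), including PRTN3 (1.84) and CST7 (1.62), and of 7 eosinophil genes EPX, CLC (1.75) and PRG3 (0.50) were (4 higher and 0 lower when adjusted over the list alone). Ribosomal protein genes (6 of 13 higher, 11 higher and 0 lower when adjusted over the list alone), unfolded protein and amino acid response genes (6 of 12 higher and CRELD2 lower at -2.34, 6 higher and 2 lower when adjusted over the list alone) and cholesterol synthesis genes (3 of 13 higher, led by SQLE at 1.15, and INSIG1 lower at -0.86, 4 higher and 1 lower when adjusted over the list alone) were higher as lists. Camera gave these 5 lists adjusted p-values of 4.15e-08, 0.0188, 4.96e-05, 0.0260 and 0.0269 in that order. The lower lists were NF-kB target genes (9 of 16, with IRF1 at -2.23 and CXCL8 at -1.95; camera adjusted p = 4.96e-05), adhesion and migration receptors (6 of 12, with FPR2 at -2.62 and CCR1 at -1.96; 0.000211) and immediate early genes (5 of 10; 0.000326). Apoptosis genes (8 of 18, with APAF1 at -1.34; camera adjusted p = 0.00299), interferon-stimulated genes (7 of 16, with IFIT3 at -1.78; 0.00505), actin regulators (3 of 14, with DOCK8 at -1.22; 0.0124) and monocyte and macrophage markers (4 of 12, with CD86 at -2.69; 0.0186) were lower too. Adjusted over the list alone, the lower members of these 7 lists numbered 9, 6, 5, 9, 8, 4 and 5 in that order. Over all genes, 1 adhesion receptor, 1 apoptosis gene and 1 interferon-stimulated gene were higher. Without both RhoH replicate 1 arrays, the lower apoptosis genes numbered 4 instead of 8 and the higher ones 2 instead of 1, the lower immediate early genes 3 instead of 5 and the higher cholesterol synthesis genes 5 instead of 3. Unfolded protein and amino acid response genes then missed camera's threshold (adjusted p = 0.0787), as they did without uninduced RhoH replicate 2 (0.0578) and with the replicate block (0.0535). Cholesterol synthesis genes missed it without uninduced RhoH replicate 2 or 3 (0.102 and 0.0525) and interferon-stimulated genes with the dimmest genes left out (0.108). Of the 12 lists, fry did not pass for cholesterol synthesis genes (0.128) and unfolded protein and amino acid response genes (0.0599). PRG3 lost its call without uninduced RhoH replicate 1 or 2 or GFP replicate 1 or 2 (adjusted p up to 0.105) and without both replicate 1 arrays (0.0829). Other named members depended on single arrays too. RPS14, RPS6 and RPL10A lost their calls without any 1 of 5, 4 and 6 arrays (adjusted p up to 0.139). HMGCS1 and MSMO1 did so for 4 and 5 arrays (0.126), FOS and EGR1 for 5 and 6 (0.128) and WAS for 5 (0.0887). Without both replicate 1 arrays, FOS (0.115), EGR1 (0.141) and WAS (0.0509) lost theirs.

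Another 9 lists did not pass camera between uninduced RhoH and GFP cells. Their called members included MYC at 1.61, CCND2 at 2.11 (0.78 at its other probe set), RET at 1.79, HP at -2.58, LAT at -2.65, KIT at -1.20 and SIAH2 at -2.03. Lymphoid markers (median 0.16, mean -0.17, camera upwards) and cell cycle genes (median 0.05, mean -0.04, camera downwards) differed in sign between measures, and the median of mast cell and basophil markers, 0.06, changed sign under scaling. Without both RhoH replicate 1 arrays, the higher mast cell and basophil markers fell from 2 to 1 and the lower transcription factors rose from 1 to 2. Mast cell and basophil markers passed camera upwards with the dimmest genes left out (0.0271), and fry passed for the transcription factors (0.00247). The count of 2258 was 4326 (2358 higher, 1968 lower) with array weights, where the balance turned to higher genes, 2798 (1342 higher, 1456 lower) after quantile normalization again, and 1556 (532 higher, 1024 lower), 1450 (528 and 922) and 1484 (504 and 980) without GFP replicate 1, 2 or 3. Without uninduced RhoH replicate 3 it was 1726 (571 and 1155). Without both RhoH replicate 1 arrays it was 2590 (1298 higher and 1292 lower), of which 2024 were called the same way with all arrays.

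As labelled, genes that moved with induced RhoH against both controls were few. The call in both comparisons with the same sign was made for 18 genes, all 18 higher and none lower in the arrays labelled induced RhoH (limma, 38 lower in both at an unadjusted p under 0.05), while 170 genes were called in both with opposite signs. With the labels of the 2 groups with 4-OHT exchanged, 603 genes would be called in both with the same sign, 395 higher and 208 lower. TSPOAP1 was 2.58-fold higher than in uninduced RhoH and 2.79-fold higher than in GFP cells, and LY96, the MD-2 co-receptor of TLR4, 4.00-fold and 2.23-fold. The basophil and mast cell protease gene CPA3 was 1.73-fold and 3.77-fold higher, the transcription factor GATA2 2.05-fold and 1.59-fold, CA2 20.2-fold and 1.56-fold, and the SLAM family receptor SLAMF6 2.73-fold and 1.53-fold. For most of these genes the 2 controls differed as well. The log2 fold change in uninduced RhoH minus GFP was 1.12 for CPA3, -3.70 for CA2 and -0.84 for LY96. It was -0.83 for SLAMF6 and -0.36 for GATA2, all called, and 0.11 for TSPOAP1 (limma adjusted p = 0.624). USP53, NRCAM, GPR85 and KIAA1549 complete the 10 genes named by the rule, with log2 fold changes between 0.55 and 0.93. TSPOAP1 and LY96 were the only 2 of the 18 genes at least 2-fold higher in both comparisons. In the alternatives run for single genes, which leave out the 2-fold condition, TSPOAP1, LY96, GATA2 and CA2 kept both calls, and KIAA1549 lost 1 only where the 6 arrays compared were fitted alone. CPA3 lost its call in the induction without both replicate 1 arrays (adjusted p = 0.0533). SLAMF6 lost its call against GFP without induced RhoH replicate 2 (adjusted p = 0.0521) and without GFP replicate 1, 2 or 3 (0.0737, 0.0792 and 0.0752). So did USP53 without GFP replicate 1 or 3 (0.0548 and 0.0530), and NRCAM without GFP replicate 1, 2 or 3 (0.0692, 0.0793 and 0.0580). GPR85 lost at least 1 of its calls when any 1 array other than induced RhoH replicate 2 was left out, in the induction without both replicate 1 arrays (0.115), and both with all probe sets tested (0.0721 and 0.0917). Where only the 6 arrays compared were fitted, USP53 (0.0678), NRCAM (0.0607), KIAA1549 (0.0570) and GPR85 (0.126) lost their calls in the induction, and GPR85 that against GFP (0.0545). Both comparisons share the induced arrays. In 100 simulations without effects that sharing gave 0.02 genes on average and at most 1. Data without effects give few calls in either comparison, so this does not measure what the sharing adds to the 18. Independent lists of these sizes would share 7.77 higher and 3.06 lower genes, but comparisons that share arrays are not independent. The fold changes of the 2 comparisons had a covariance of -0.0136 across genes, against a simulated 0.00988, and a correlation of -0.20 against a simulated 0.50. The count of 18 was 6 where only the 6 arrays compared were fitted, 31 (1 of them lower) after quantile normalization again and 39 (5 lower) with array weights. It was 11 without uninduced RhoH replicate 2 or 3 and 8, 9 and 7 without GFP replicate 1, 2 or 3, and 31 (1 lower) without both RhoH replicate 1 arrays, with 12 of the 18 among them. That none was lower did not hold either without uninduced RhoH replicate 1 (18, with 1 lower), induced RhoH replicate 2 (27, with 6 lower) or induced RhoH replicate 3 (19, with 3 lower).

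The genes called in RhoH cells with 4-OHT mostly went the same way in GFP cells with 4-OHT, both set against the same uninduced RhoH arrays. Of the 558 genes, 548 (98.2%) had the same sign in GFP minus uninduced RhoH, against a mean of 89.2% and at most 92.5% for the 558 genes of lowest p in simulations without effects that share the uninduced arrays. Of the 558, 517 were also called there, 413 higher and 104 lower. CA2, CCL2 and JUN were among the higher ones. With the labels of the 2 groups with 4-OHT exchanged, the induction would be the comparison with 2258 called genes. Of these, the same 517 were called the same way in the other group. Independent lists of the sizes called in these 2 comparisons would share 41.4 higher and 6.67 lower genes, although shared arrays break independence. The same simulations gave 0.03 genes on average and at most 1. Data without effects give few calls, so this does not measure what the sharing adds to the 517. The covariance of the 2 sets of fold changes across genes was 0.0768 against a simulated 0.00984, and the correlation 0.76 against 0.50. Noise in these simulations was independent between genes. The 3 uninduced arrays were not split between the 2 comparisons, so part of the excess in overlap may come from sharing them. Conversely, 603 genes set GFP apart from both RhoH groups in the same direction, 208 lower in GFP cells, such as EPX, PRTN3 and CTSG, and 395 higher in GFP cells, such as CEMIP2, CDON and FPR2. The 2 comparisons behind this count share the GFP arrays, so part of it may come from their noise.

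**Figure D3:**
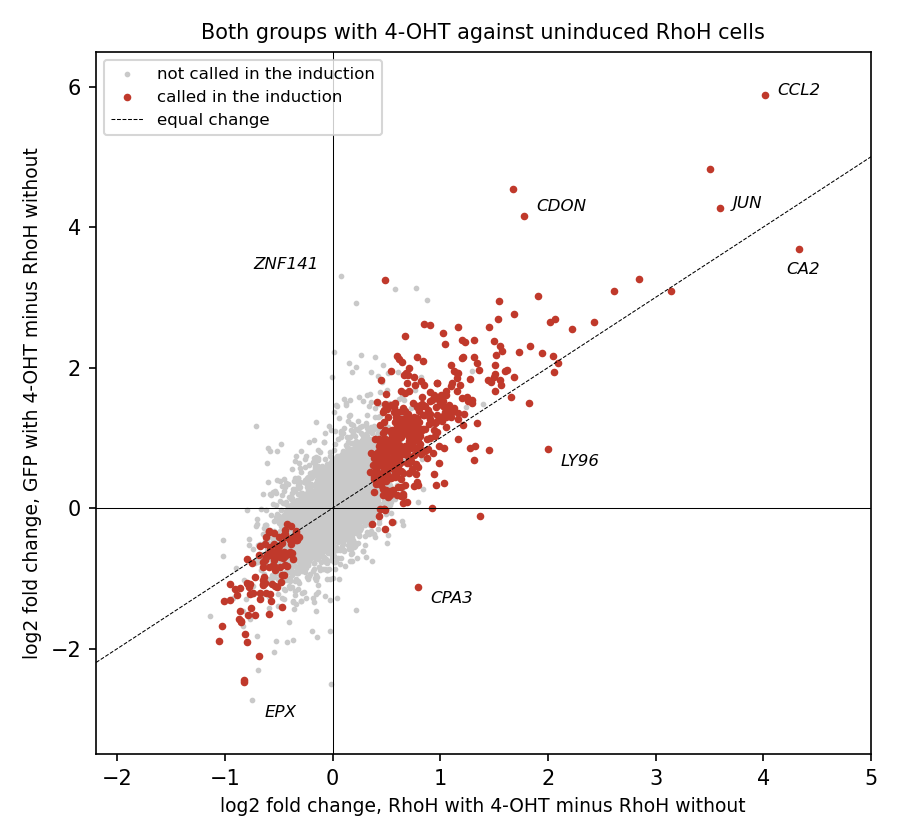
Log2 fold change of each of the 14778 genes in RhoH cells with 4-OHT (horizontal) and in GFP cells with 4-OHT (vertical), both minus RhoH cells without 4-OHT. Points are genes, red where called in RhoH cells, and the dashed line marks equal change; 548 of the 558 red points have the same sign on both axes, whose noise is partly shared through the uninduced arrays.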

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

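The naming table leaves 27891 of the 43550 probe sets unnamed, and the comparisons by gene do not use them; tested together with the named ones by limma they too held differences. In induced against uninduced RhoH, 204 unnamed probe sets were called, 177 higher and 27 lower. In induced RhoH against GFP 358 were called, 93 higher and 265 lower, and in uninduced RhoH against GFP 1312, 459 higher and 853 lower. The called share was 0.731%, 1.28% and 4.70% of the unnamed probe sets, against 2.06%, 2.64% and 11.05% of the named ones in the same fit. In both comparisons of induced RhoH 4 unnamed probe sets were called, all higher, led by 16849933 (log2 fold changes 1.21 and 0.83) and 17055263 (0.69 and 1.00). Whether these lie in genes was not analysed here.

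All tests of explanations below except that of an exchange of the replicate 1 arrays were chosen after the result was seen; the splits of the arrays were planned. The tests of the replicate 1 arrays as the source of the shared direction and of a narrower signal range replaced earlier ones whose outcomes had been seen, given here beside them.

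Mean RHOH was higher in the arrays labelled GFP than in those labelled induced RhoH, though not past the threshold. That order goes against the labels only if the probe set reads the construct's transcript. An exchange of the labels of the 2 groups with 4-OHT stays open: the difference of -0.33 (adjusted p = 0.0717) is the observation that raised the question, so it does not bear on an exchange, and no other value here was found to decide it. RHOH might also respond to 4-OHT or to the 4-OHT-dependent activator whatever the construct: GFP with 4-OHT minus uninduced RhoH was 0.72, but without untreated GFP arrays this cannot be told apart from a difference between the transduced populations. A probe set that reads little of the construct's transcript is a further candidate explanation, since induction changed RHOH by only 0.38 on the log2 scale; probe positions were not used here, and this stays open. A biological difference between the RhoH and GFP populations in their own RHOH was not tested.

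The fold changes of RhoH cells with 4-OHT followed those of GFP cells with 4-OHT against the same uninduced arrays. Shared noise of those arrays that is independent between genes does not account for it, since the covariance was 0.0768 against at most 0.0112 in 100 simulations without effects. Deviations of an array that run across many genes were not simulated, so shared noise of that kind is not excluded. The deviating replicate 1 arrays do not account for it either: without both, the covariance was 0.0710 against at most 0.00947 in simulations on the 7 arrays left. The earlier test, by which 98.6% of the 557 genes called without them went the same way, says less, as simulations without effects gave up to 94.4%. An effect of 4-OHT or of its activator common to both constructs may account for it and would give a high share of genes going the same way. That share was 98.2%, but the shared arrays alone gave 89.2% on average in simulations without effects, so little weight is put on it. With no untreated GFP arrays this cannot be told apart from properties of the uninduced RhoH cultures, and a biological effect of RhoH itself is not separated from either.

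The replicate 1 arrays of both RhoH groups deviated together from their group means, with a correlation of 0.543 across genes. Induced RhoH replicate 3 deviated as much from its own group, at -0.14 with uninduced RhoH replicate 1, and no explanation of that was tested. The 2 replicate 1 arrays had a narrower signal range, with an SD over the tested genes of 1.93 and 1.94 against 2.01 to 2.04 on the other 7, which the earlier test took as going with this explanation, but quantile normalization of these genes, which gives all arrays one range, left the correlation at 0.466, so the range is not the whole cause and may be part of it. An exchange of these 2 arrays with each other is argued against, since over the genes called without them the median difference between the 2 arrays in the direction of the other replicates was 0.73 on the log2 scale, with 97.1% of the genes going that way. A different share of intron and short RNA signal could not be settled, as miRNA genes exceeded protein-coding genes in their median deviation by 0.0298 and 0.0523. No batch is given in the labels, and no biological explanation was tested.

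With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The 558 genes of the induction were reached by 1 of the 10 splits, the real one, and the highest other count was 59, for uninduced replicate 1 with induced replicates 1 and 3 against the rest. In RhoH against GFP the real 664 stood against a highest other count of 0 (1 of 10 splits as large), and in uninduced RhoH against GFP 2258 stood against 0 (1 of 10). For the 18 genes called in both comparisons, 100 splits of the 9 arrays into 3 groups of 3 were drawn, the real one included, and 1 gave as many, with a highest other count of 1. The other splits mix groups that differ in many genes, which widens the spread within their groups: the median SD was 0.151 to 0.176 against 0.143 in the real split, wider in 99 of 99. They would call few genes for that reason alone, so a chance split of the arrays is left open by this test.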

How the results depend on the processing

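The settings that left out both RhoH replicate 1 arrays or kept protein-coding genes only were chosen after seeing the data; the others were planned. RHOH and the lists did not turn direction while called, but the balance of higher and lower genes did. Against GFP, higher genes became the majority without induced RhoH replicate 1 (319 of 615) and without both replicate 1 arrays (512 of 990), and in uninduced RhoH with array weights (2358 of 4326) and without both replicate 1 arrays (1298 of 2590). The counts of 558, 664, 2258 and 18 stayed within 1.5 times, and RHOH kept its side of the threshold in both comparisons, with the trend and robust prior, the replicate block and protein-coding genes only. With the replicate block the counts were 684, 820, 2558 and 24 (3 of them lower) and RHOH kept its fold changes of 0.38 and -0.33; same-numbered uninduced and induced arrays deviated together with correlations of 0.54, 0.37 and 0.07, against 0.40 between uninduced 3 and induced 2. Same-numbered RhoH and GFP arrays of replicates 1 and 2 were at 0.10, 0.15, 0.13 and 0.15, the highest of all RhoH and GFP pairs, and those of replicate 3 at 0.01 and -0.03. Whether the numbers pair the cultures is left open. RHOH was among the dimmest 40% and has no value without them.

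Quantile normalization again gave 953 genes in the induction, 31 in both and -0.37 for RHOH against GFP, now past the threshold (adjusted p = 0.0467). Array weights, which favoured arrays close to their group, gave 950, 1176, 4326 and 39. Fitting only the 6 arrays compared gave 190 in the induction and 6 in both, but 2833 in uninduced RhoH against GFP. A fold change of at least 2 as well left 102, 116, 464 and 2, by construction. RHOH in the induction missed the threshold with all probe sets tested (0.38, adjusted p = 0.112, more tests), with only the 6 arrays (0.38, adjusted p = 0.192), with arrays centred on their median (0.36, adjusted p = 0.0776) and without both replicate 1 arrays (0.39, adjusted p = 0.109), where 31 genes were called in both. Its adjusted p over the alternatives ran from 0.00542 to 0.192. Except where stated, the cause was not tested.

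Leaving out 1 array at a time gave 304 to 666 genes in the induction, 279 to 861 in RhoH against GFP, 1450 to 2670 in uninduced RhoH against GFP and 7 to 27 in both. RHOH ranged from 0.32 to 0.45 (adjusted p = 0.0184 to 0.171) in the induction and from -0.40 to -0.26 (adjusted p = 0.0495 to 0.236) against GFP, called there only without induced RhoH replicate 2. Of 308 named values, 197 called, 2822 of the values under the alternatives kept their side of the threshold, 129 passed it and 90 no longer did, and with 1 array left out 2512 kept it, 30 passed and 230 no longer did. Of 66 list values, 27 called, the numbers were 334, 12 and 50, and with 1 array left out 558, 11 and 25. The estimated correlation ended 26 of the 27 list calls. Signal near background limits the dimmest genes, whose fold changes RMA compresses.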

Other observations

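All gene groups in this part were chosen after the values were seen, and the tests of such groups are no independent evidence. Toll-like receptors and their co-receptors were partly higher with 4-OHT in RhoH cells as labelled: of 13 measured, TLR1 (1.13 on the log2 scale, adjusted p = 0.00104), TLR6 (1.54, adjusted p = 0.000274), LY96 (2.00) and CD180 (0.63, adjusted p = 0.0381) rose and none fell by limma. TLR1 and TLR6, the partners of TLR2 in the recognition of lipopeptides, were lower in induced RhoH than in GFP cells (-0.82 and -1.16), as was CD14 (-1.35), while LY96 was higher (1.16). TLR2 itself was at -0.10 and -0.07 and TLR4 at 0.11 and 0.08 in the 2 comparisons, none of them past the threshold. Camera over the 3 groups chosen here gave the 13 genes an adjusted p of 5.17e-05 for the induction (0.0353 with an estimated correlation) and of 0.068 for RhoH against GFP. In uninduced RhoH minus GFP, 6 of the 13 were lower and none higher, with TLR1 at -1.95, TLR6 at -2.70 and LY96 at -0.84. CD180, at -0.17, did not pass there. Camera gave that comparison an adjusted p of 0.000196 (0.0435 with an estimated correlation).

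Of 8 measured SLAM family receptors, which sit on the surface of leukocytes and bind one another, CD48 (2.23), SLAMF6 (1.45) and CD84 (1.33, adjusted p = 0.000332) rose with 4-OHT in RhoH cells and none fell (camera adjusted p = 0.000104, and 0.0353 with an estimated correlation). All 3 were also higher in GFP with 4-OHT than in uninduced RhoH cells, and SLAMF6 alone was also higher in induced RhoH than in GFP (0.62, with CD84 at 0.44 and an adjusted p of 0.0876). Of 3 measured guanylate-binding proteins, GBP3 and GBP4 were at -2.76 and -3.13 in uninduced RhoH minus GFP and at -1.07 and -2.35 in induced RhoH minus GFP, all called, and GBP5 was not called in any comparison. With 4-OHT in RhoH cells GBP3 rose (1.69, adjusted p = 0.00368) and GBP4 was at 0.78 (adjusted p = 0.120). Over the 464 genes at least 2-fold apart between uninduced RhoH and GFP, the induced RhoH arrays lay at a median of 49.9% of the way from uninduced RhoH to GFP, a position that noise shared between the groups can move.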
